A study of Mus musculus with 6 samples.

How the data were processed

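RNA-seq libraries came from the cerebellum of male mice at 6 weeks of age, 3 labelled wild type and 3 labelled heterozygous for a Reln null allele. Group and replicate number were taken from the sample titles. Total RNA was extracted with an RNeasy column, libraries were made with a stranded total RNA kit, and single-end reads were sequenced on an Illumina NextSeq, per the labels' protocols.

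The authors' values are FPKM, which scales each gene's fragments by its exon length and the size of the library, 1 library per file, per the labels' protocols. The file headers name the column rpkm, which for single-end reads is the same unit. Mitochondrial and ribosomal sequences had been filtered out, 2 bases trimmed from the start of each read, reads aligned to mm10 with TopHat2 and the Bowtie 1 aligner, and genes quantified with Cufflinks, per the labels' protocols. Cuffdiff 2.1.1 was used by the authors for their own heterozygous against wild-type test, per the labels' protocols; that test was not used here. Full versions of TopHat2, Bowtie and Cufflinks, the annotation release and the strand setting of the quantification are not given in the sources used here. FPKM divides by the size of the library, so RNAs whose share of the reads differs between libraries can shift the values of all other genes. For small RNAs only the share of the summed FPKM was measured, not the share of reads, so the size of such a shift is not known.

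Every file listed the same 24537 genes, so using only genes listed in all files, an alternative set beforehand, changed nothing. In the file of heterozygous replicate 2, 40 values read as spreadsheet dates; the value of those genes is unknown there, and they were left out of every test. In wild-type replicates 2 and 3 some values, 316 and 361, had been rewritten with 3 digits. The 2 genes Hbb-bt and Hbb-b2 had identical values in every library.

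FPKM is not a count, and whole reads could not be recovered in a form that a count test needs, so the planned count test was not run. Low FPKM values fell in steps of whole reads, which gave each library's relative depth. With transcript lengths of 4050 single-transcript genes from GENCODE M21 (GRCm38, the assembly also called mm10), this gave approximate depths of 28360000, 26820000 and 28600000 reads in wild-type replicates 1, 2 and 3 and of 25100000, 27080000 and 22860000 in heterozygous replicates 1, 2 and 3. No correction for effective length was made, so read numbers derived from them are approximate and counting errors cover sampling only. Of the 24537 genes, 97.1% matched 1 position in that annotation, which gave the coordinates, identifiers and overlapping genes.

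Genes with a mean of at least 1 FPKM over the 6 libraries (6358 genes) were tested on log2(FPKM + 1), with FPKM as deposited, by limma 3.58.1 in R 4.3.3 with an intensity trend and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. A log2 value in the text is the difference in mean log2(FPKM + 1), heterozygous minus wild type, which understates the change of genes with low FPKM. Reln and P4hb were also compared by a two-sided exact permutation test, which cannot go below 0.1 with 3 against 3 libraries. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The test was tested on simulated data, 10 runs of this comparison with 6358 genes and known changes. It recovered 23.1% of 1.5-fold, 88.4% of 2-fold and 99.5% of 4-fold changes, all with the right sign. On average it made 17.5 false calls per run where 200 genes had changed, and 0.9 calls per run where none had. Where 200 genes had changed, the false calls were a larger share of all calls than the 0.05 that the adjusted p is meant to hold. The simulated noise was independent between genes apart from a shift per library. Splits of the actual libraries other than the real split gave 0 to 92 calls, so the simulated rates need not hold for this comparison.

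Gene lists were tested with camera at a preset correlation of 0.01 between genes, which asks whether a list lies above or below the other tested genes, with Benjamini-Hochberg adjustment over the 28 lists that had at least 5 tested members; camera with an estimated correlation was run beside it, and fry, which tests each list against no change and not against other genes. The 34 lists covered the reelin pathway, protein disulfide isomerases, the unfolded protein response, cerebellar and other cell types, adjacent tissues, neuronal activity, clock, hormone and interferon responses, synapse and matrix, autism risk genes, RNA classes, and gene families that vary between strains. Groups, tests, lists, the rule for named genes and the alternatives were set before the data were examined, except 4 alternatives named in the closing section.

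Named genes were Reln, Vldlr, Lrp8, Dab1 and P4hb; then, among genes past the threshold whose groups did not overlap, the 10 largest rises, the 10 largest falls and the 10 most abundant; then up to 4 members of each list with the smallest p. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were taken and said not to pass. Gene models and small RNAs were counted and not named, except those called here.

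The alternatives were pseudocounts of 0.1 and 0.01, no filter and a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, small RNA genes left out, limma without the trend, limma with array weights, the replicate number as a block, a covariate for the set of files with blank rows at the end, and each library left out in turn. No sequencing batch is given in the labels. That set of files held heterozygous replicate 2 and wild-type replicates 2 and 3, too few of either group for a comparison within it. Only wild-type replicates 2 and 3 had values rewritten with 3 digits. Their summed FPKM, 55097.9 and 55043.2, lay below the 61859.3 to 64726.1 of the other libraries. No heterozygous library had these traits, so the covariate does not separate them from the group.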

Results

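Gene expression was measured by RNA-seq in the cerebellum of male mice at 6 weeks of age. There were 3 libraries from mice heterozygous for a null allele of Reln and 3 from wild-type mice. Reln encodes reelin, a secreted glycoprotein that guides neuronal positioning through the receptors Vldlr and Lrp8 (ApoER2) and the adaptor Dab1. The strain label differed between the groups in every library, C57BL/6 for wild type and Orl/BalbC for heterozygous, so each difference below is one of genotype and labelled strain together. The labels do not say whether the libraries of a group came from separate animals, and p-values refer to these libraries. In limma, the SE and p of a gene rested mostly on the spread of other genes of like level. The trend over genes held 54.4 degrees of freedom, against 4 from the gene's own libraries. The files held FPKM values for 24537 genes, and the steps between low values gave approximate depths of 28360000, 26820000 and 28600000 reads for wild-type replicates 1, 2 and 3, and of 25100000, 27080000 and 22860000 reads for heterozygous replicates 1, 2 and 3.

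The first question was whether Reln and its pathway differed between heterozygous and wild-type cerebellum. Reln (ENSMUSG00000042453, chromosome 5, 21884454 to 22344702, minus strand, mm10) was lower in all 3 heterozygous libraries. Its level was 0.848 ± 0.086 FPKM in wild type (SD, n = 3) and 0.540 ± 0.037 FPKM in heterozygous cerebellum (SD, n = 3), a ratio of 0.636. The lowest wild-type library had 0.771 FPKM and the highest heterozygous library 0.580 FPKM. The difference in mean log2(FPKM + 1) was -0.26, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. At about 155 to 315 reads per library, counting error was 5.64% to 8.03% of the value, which leaves out the spread between libraries. Reln lay under the mean of 1 FPKM set for the test over all genes and was not part of it. When that minimum was lowered to 0.5 FPKM, its adjusted p in limma was 0.78.

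The reelin receptors did not differ by more than the spread between replicates. Vldlr stood at 4.13 ± 0.70 FPKM in wild type and 4.16 ± 0.44 FPKM in heterozygous cerebellum (SD, n = 3 each), a log2 difference of 0.016 (SE 0.13, limma adjusted p = 0.98). It turned to -0.077 after median-of-ratios scaling. Lrp8 stood at 1.04 ± 0.10 and 1.03 ± 0.11 FPKM (limma adjusted p = 0.99). Dab1 was low in both groups, at 0.225 ± 0.046 and 0.196 ± 0.029 FPKM (SD, n = 3 each, exact permutation p = 0.3). Of the 21 reelin pathway genes tested, 17 had a higher and 4 a lower mean in heterozygous libraries, and none passed the test, over all genes or adjusted over the list alone. Cdk5, a kinase that acts in neuronal migration, had the largest value, 0.20 (SE 0.15). The median of the list was 0.049, below the median of all tested genes, and camera gave a direction of lower with an adjusted p of 0.50.

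**Figure D1:**
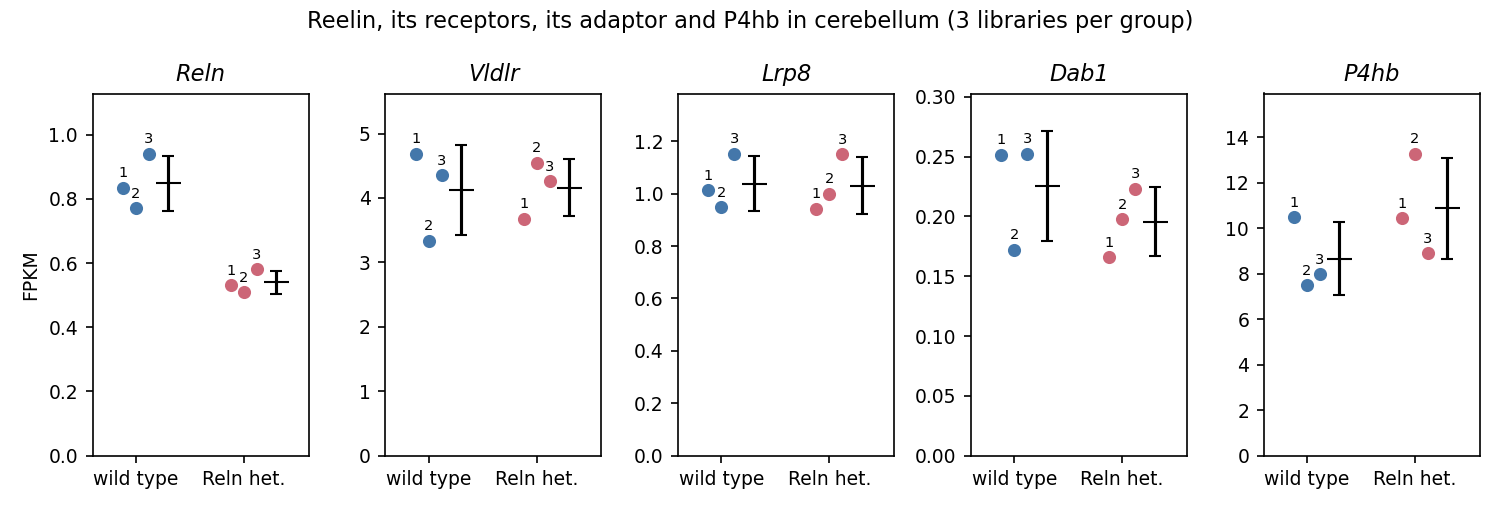
FPKM of Reln, Vldlr, Lrp8, Dab1 and P4hb in each library (points, numbered by replicate) of wild-type and Reln heterozygous cerebellum, with the mean and SD of 3 libraries beside them. The Reln values of the groups do not overlap (lowest wild type 0.771, highest heterozygous 0.580 FPKM), and those of the other 4 genes do.

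Because the series title names protein disulfide isomerase, P4hb and related genes of the endoplasmic reticulum were compared next. P4hb (ENSMUSG00000025130, chromosome 11, 120560298 to 120573253, minus strand), which encodes protein disulfide isomerase, stood at 8.65 ± 1.61 FPKM in wild type and 10.9 ± 2.2 FPKM in heterozygous cerebellum (SD, n = 3 each). The log2 difference was 0.29 (SE 0.15), and the groups overlapped (two-sided exact permutation p = 0.3, limma adjusted p = 0.90). The difference was 0.15 without heterozygous replicate 2, and 0.067 without both that library and wild-type replicate 2. All 12 protein disulfide isomerase family genes tested had a higher mean in heterozygous libraries, as did 83.1% of all tested genes, with a median of 0.17 against 0.083, and none passed the test singly or adjusted over the list alone. Of the 12 family genes, Pdia6 (0.27), Tmx2 (0.25) and Tmx1 (0.20) came next to P4hb. As a group they lay above the other genes in camera (adjusted p = 0.043), a call that was lost with an estimated correlation (adjusted p = 0.91 with an estimated correlation).

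Genes of the unfolded protein response showed a similar picture with 1 member that passed. Chac1, which encodes a glutathione-degrading enzyme induced downstream of Ddit3, rose by 0.53 (SE 0.12, limma adjusted p = 0.039). It stood at 0.605, 0.760 and 0.770 FPKM in wild type and at 1.19, 2.73 and 0.849 FPKM in heterozygous replicates 1, 2 and 3, and without heterozygous replicate 2 its mean lay below the minimum for testing. Of 24 genes tested, 23 had a higher mean in heterozygous libraries (83.1% of all tested genes had), with a median of 0.19; 1 rose over all genes and 2 rose adjusted over the list alone. Ddit3, the transcription factor CHOP, had a value of 0.41 (SE 0.13, limma adjusted p = 0.57) with groups that did not overlap, while the chaperone genes Sdf2l1 (0.33) and Creld2 (0.25) overlapped. The list was called higher by camera (adjusted p = 0.0071; adjusted p = 0.91 with an estimated correlation). Without wild-type replicate 2 and heterozygous replicate 2, the libraries at the ends of the first principal component, neither group was called (adjusted p = 0.82 for the isomerases and 0.79 for the unfolded protein response).

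Across the transcriptome few genes differed between heterozygous and wild-type cerebellum. Of 6358 genes with a mean of at least 1 FPKM, 5 passed an adjusted p of 0.05 in limma, 1 higher and 4 lower in heterozygous libraries. The higher gene was Chac1 (chromosome 2, 119351229 to 119354381). Zfhx2os (chromosome 14, 55053869 to 55075873), an antisense transcript of the homeobox gene Zfhx2, fell by 0.65 on the log2 scale (SE 0.12, adjusted p = 0.0074), from 2.60 ± 0.77 to 1.29 ± 0.50 FPKM (SD, n = 3 each). The other 3 were named after their values were seen, since they fall outside the rule for named genes. Snora31 (chromosome 14, 75847905 to 75848034), a small nucleolar RNA within the span of Tpt1, fell by 0.89 (SE 0.14, adjusted p = 9.8e-05). Snord15a (chromosome 7, 99482785 to 99482932), another within the span of Rps3, fell by 0.70 (SE 0.14, adjusted p = 0.014), and the processed pseudogene Gm3219 (chromosome 14, 34345281 to 34345583) fell by 0.61 (SE 0.13, adjusted p = 0.038). Wild-type and heterozygous values overlapped for Zfhx2os and Snord15a. Reads of these 4 genes can be shared with a host, a partner on the opposite strand or a near-identical copy, so their levels are uncertain. Without a correction for effective length, Snora31 had about 2.3 to 12.8 reads per library (counting error 28% to 65.7%), Snord15a 2.0 to 15.0 (25.8% to 70.8%) and Gm3219 9.1 to 35.9 (16.7% to 33.2%), against 28.1 to 120.9 for Chac1 (9.1% to 18.9%) and 94.2 to 379.6 for Zfhx2os (5.1% to 10.3%). The SE of these calls also depended on which genes were tested with them. With no filter on low values it was 0.27 for Chac1, 0.22 for Zfhx2os, 0.30 for Snora31, 0.32 for Snord15a and 0.22 for Gm3219. None of the 5 passed there (limma adjusted p = 0.97 for each).

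Of the genes with the smallest p in each direction that the rule names, the following did not pass. Higher means in heterozygous libraries were seen for Zcchc12 (0.56, adjusted p = 0.066), for the interneuron peptide gene Sst (0.44, adjusted p = 0.10), for the linker histone gene Hist1h1b (0.52, adjusted p = 0.22) and for Fibin (0.42, adjusted p = 0.52). Lower means were seen for the imprinted noncoding RNA Meg3 (-0.65, adjusted p = 0.090), the potassium channel subunit gene Kcne2 (-0.72, adjusted p = 0.20), the olfactory receptor pseudogene Olfr856-ps1 (-0.72, adjusted p = 0.20) and the neuronal transcript Snhg11 (-0.53, adjusted p = 0.20). At an unadjusted p under 0.05 there were 212 genes, against 317.9 by chance, and in 353 of the 6358 genes (5.55%, against 10% by chance) the groups did not overlap in FPKM as deposited, a share that was 10.9% (692 genes) after median-of-ratios scaling. Of all genes tested, 83.1% had a higher mean in heterozygous libraries, with a median of 0.083. The median moved to -0.0014 after median-of-ratios scaling and to -0.019 when small RNA genes were left out and the rest rescaled. After either step, or quantile normalization, 0 genes passed in limma (325, 225 and 344 at an unadjusted p under 0.05). Without wild-type replicate 2 none of the 5 genes was among the 5 that then passed. Rescaling after leaving out small RNA genes also set the summed FPKM equal, so that step does not single out small RNAs. The sums were 62803.9, 55097.9 and 55043.2 in wild-type replicates 1, 2 and 3 and 61859.3, 63812.5 and 64726.1 in heterozygous replicates 1, 2 and 3. Small RNA genes took 0.766% to 2.29% of the sum.

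**Figure D2:**
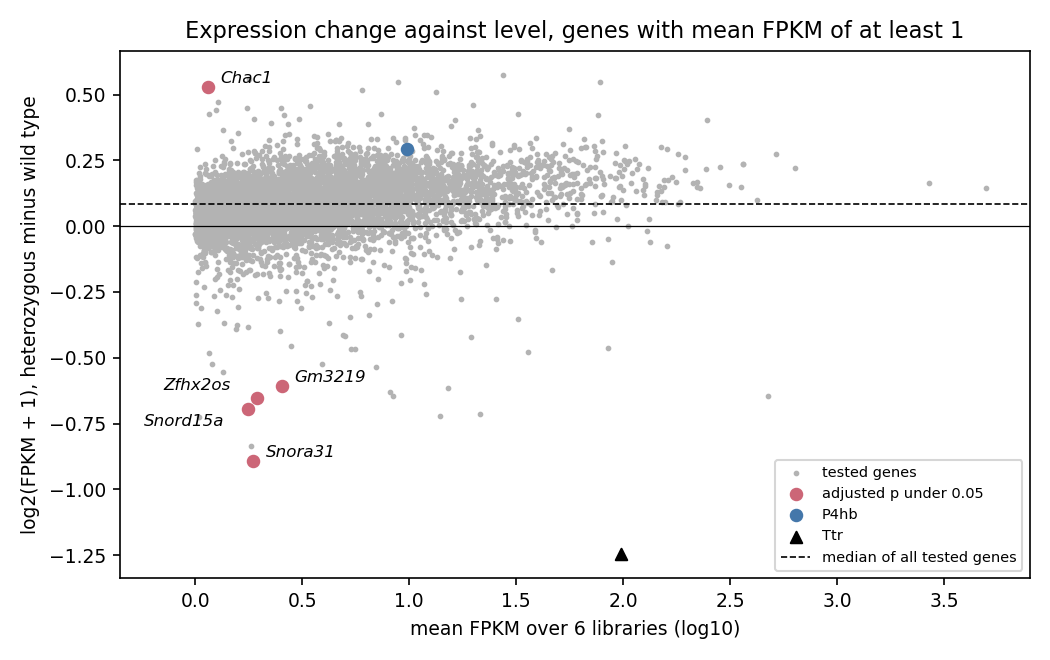
Difference in mean log2(FPKM + 1), heterozygous minus wild type, against the mean FPKM over 6 libraries (log10) for the 6358 genes tested; the dashed line is the median of all of them, 0.083. The 5 genes with an adjusted p under 0.05 (red) have a mean of under 3 FPKM, P4hb (blue) lies at 0.29, and Ttr (triangle) has the lowest value, -1.25, but does not pass (adjusted p = 0.90).

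Of 34 gene lists fixed before the data were examined, 28 had at least 5 tested members. With camera's preset correlation 13 of these were called, 6 higher and 7 lower than the other genes; with an estimated correlation 0 were called. By fry, which asks whether a list's genes move on balance 1 way and does not compare them with other genes, 0 were called. Against 83.1% of all tested genes, cytosolic ribosomal protein genes were higher in heterozygous libraries in 80 of 82 cases, with a median of 0.20 (adjusted p = 1.3e-13; adjusted p = 0.91 with an estimated correlation). Examples were Rps14 (14.0 ± 0.9 against 18.8 ± 2.0 FPKM), Rps13 (18.0 ± 2.0 against 22.9 ± 3.0 FPKM) and Rps18 (21.7 ± 1.9 against 27.1 ± 1.8 FPKM; SD, n = 3 each), none of which passed the test. Nuclear genes of oxidative phosphorylation were higher in 85 of 86 cases, with a median of 0.19 (adjusted p = 1.0e-09; adjusted p = 0.91 with an estimated correlation). Sdhd of complex II (0.34), Cyc1 of complex III (0.34) and the complex III assembly factor Uqcc2 (0.25) were among them, and none of the 86 passed. Both lists kept a median above that of all genes under each scaling.

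Replication-dependent histone genes were higher in 36 of 43 cases, close to the 83.1% of all tested genes, with a median of 0.21 (camera adjusted p = 2.7e-06; adjusted p = 0.91 with an estimated correlation). None passed over all genes, and 7 rose and 1 fell adjusted over the list alone. Hist1h1d went from 21.8 ± 6.2 to 32.8 ± 7.8 FPKM and Hist1h2ac from 1.28 ± 0.44 to 1.88 ± 0.24 FPKM (SD, n = 3 each); reads of near-identical histone genes cannot always be told apart. Long noncoding RNAs held in the nucleus went the other way. Of 9 tested, 7 had a lower mean in heterozygous libraries, with a median of -0.092 and a mean of -0.22 (camera adjusted p = 2.3e-11; adjusted p = 0.17 with an estimated correlation), and 4 fell adjusted over the list alone, none over all genes. Malat1 stood at 583 ± 137 FPKM in wild type and 368 ± 62 FPKM in heterozygous cerebellum, and Kcnq1ot1 at 1.23 ± 0.63 and 0.780 ± 0.220 FPKM (SD, n = 3 each). The groups overlapped for both. Wild-type replicate 1 had 426 FPKM of Malat1 and 0.598 of Kcnq1ot1, against 428 and 1.01 in heterozygous replicate 1. Wild-type replicates 2 and 3 were highest, at 677 and 646 FPKM of Malat1 and 1.85 and 1.23 of Kcnq1ot1. Snhg11, annotated as protein coding in GENCODE M21, stood at 8.44 ± 0.90 and 5.55 ± 1.00 FPKM (SD, n = 3 each) with no overlap. The share of the summed FPKM taken by small and structural RNA genes ranged from 10.2% to 21.6% in wild type and from 7.36% to 21.7% in heterozygous libraries, with wild-type replicate 2 and heterozygous replicate 3 highest.

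**Figure D3:**
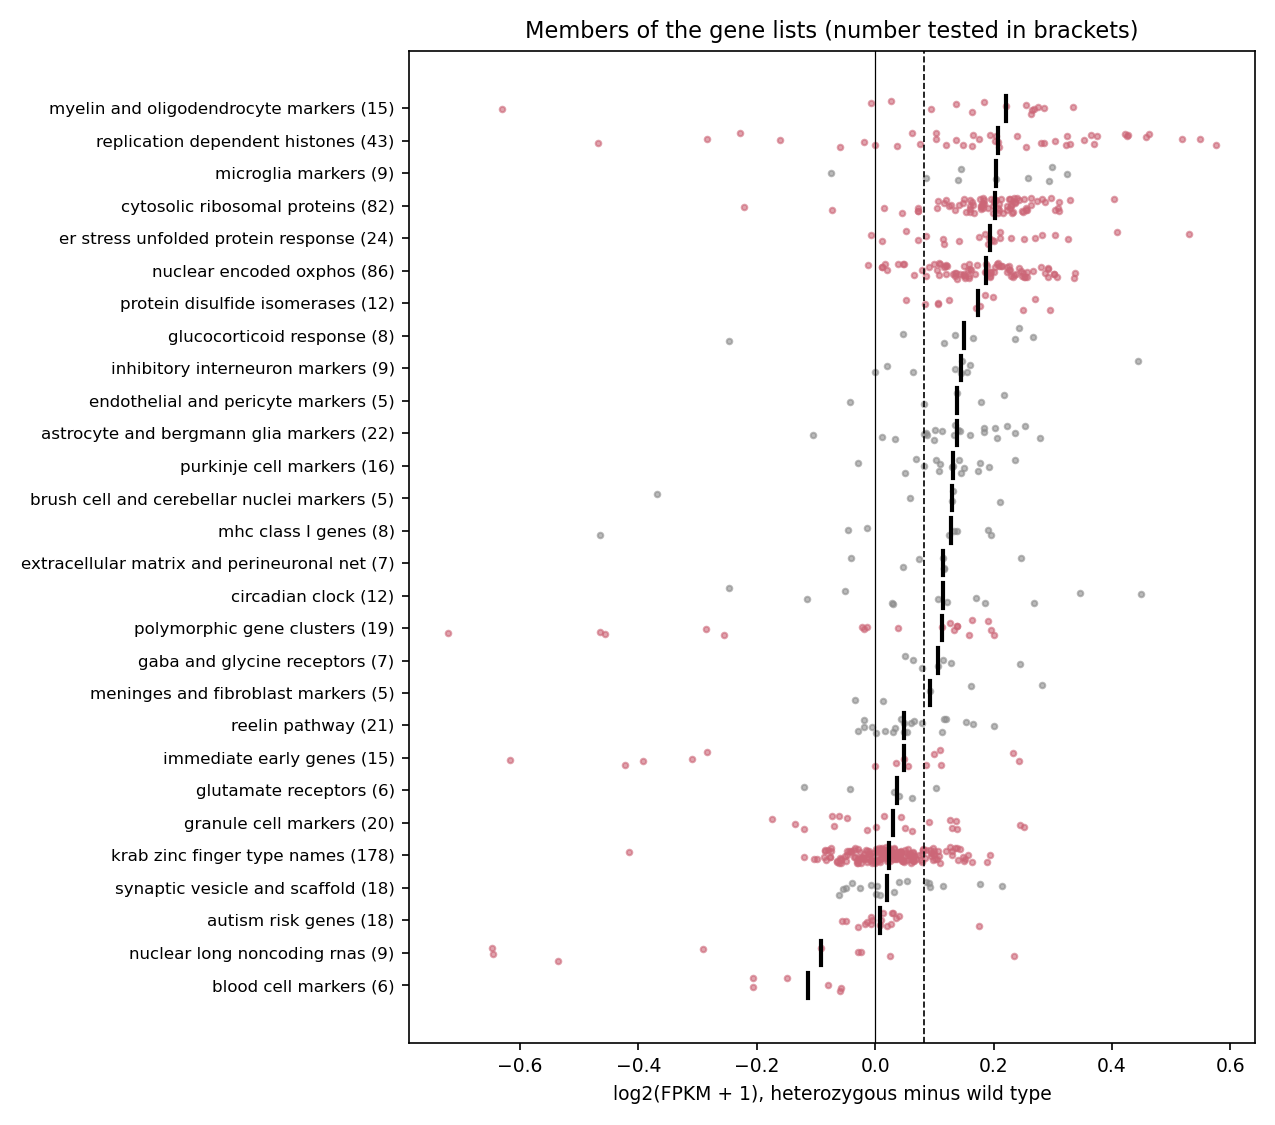
Difference in mean log2(FPKM + 1), heterozygous minus wild type, for each tested member (points) of the 28 gene lists with at least 5 tested members; black bars are list medians and the dashed line is the median of all tested genes, 0.083. Red lists passed camera with its preset correlation, and none passed with an estimated correlation; ribosomal protein genes have a median of 0.20 and nuclear long noncoding RNAs one of -0.092.

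Markers of the cerebellar cell types differed little. The 20 granule cell markers had a median of 0.030, with 12 higher and 8 lower in heterozygous libraries. They were called lower than the other genes although their median and mean were above 0 (camera adjusted p = 0.043, and 0.91 with an estimated correlation). This call was lost without wild-type replicate 1, 2 or 3. It was also lost without heterozygous replicate 2, where their median lay 0.023 above that of all genes. Gabrd, a granule cell GABA receptor subunit gene, had a value of 0.24 (SE 0.15). Purkinje cell markers (16, median 0.13, adjusted p = 0.21), among them Gng13 (0.19), inhibitory interneuron markers (9, median 0.14, adjusted p = 0.27), among them Pvalb (0.16), and astrocyte and Bergmann glia markers (22, median 0.14, adjusted p = 0.15), among them Gdf10 (0.21), were not called. In these lists no gene passed over all genes, and Sst alone rose adjusted over the list alone. Markers of unipolar brush cells and the cerebellar nuclei (5, median 0.13) had camera's direction lower, against their median, with an adjusted p of 0.47. Myelin and oligodendrocyte markers (15, median 0.22), 13 higher and 2 lower in heterozygous libraries, were called higher (camera adjusted p = 0.031, and 0.91 with an estimated correlation). That call was lost without heterozygous replicate 2 or 3 or wild-type replicate 2 or 3. Mal was at 0.33 (SE 0.15), Mog at 0.26 (SE 0.13) and Enpp2, the other way, at -0.63 (SE 0.32), none past the test. Enpp2 stood at 10.98 to 18.9 FPKM in wild-type replicates 1 and 3 and heterozygous replicate 2. It was at most 2.57 FPKM in the other libraries. The choroid plexus gene Ttr split the libraries in the same way (below), so the lower mean of Enpp2 cannot be read as one of myelin. Microglia markers (9, median 0.20, adjusted p = 0.13) had C1qb at 0.32 (SE 0.11), and 1 gene rose adjusted over the list alone. Endothelial and pericyte (5, median 0.14, adjusted p = 0.91) and meningeal (5, median 0.092, adjusted p = 0.99) markers were not called. All 6 blood cell markers, of which Hbb-bt and Hbb-b2 held identical values and so count 1 measurement 2 times, had a lower mean (median -0.11, adjusted p = 0.0015; adjusted p = 0.91 with an estimated correlation), a direction that turned without wild-type replicate 1 (median 0.18 above that of all genes).

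Markers of neighbouring tissue differed within both groups. Ttr, the transthyretin gene expressed by choroid plexus, stood at 273, 0.566 and 150 FPKM in wild-type replicates 1, 2 and 3 and at 3.15, 156 and 6.43 FPKM in heterozygous replicates 1, 2 and 3. The choroid plexus genes Kcne2, Sostdc1 and Kcnj13 were likewise higher in wild-type replicates 1 and 3 and heterozygous replicate 2 than in the other 3 libraries. So was Enpp2, counted above among the myelin markers. The 4 tested choroid plexus markers, too few for camera, had lower means in heterozygous libraries (median -0.78). None passed over all genes and 3 fell adjusted over the list alone. The groups overlapped for these 3, Kcne2, Sostdc1 and Kcnj13. Their SE was 0.19, 0.27 and 0.19, against 0.58, 0.82 and 0.56 with no filter on low values. Of the other lists under 5 tested genes, granule cell precursor and proliferation genes had 3 (median 0.076, with 1 that fell adjusted over the list alone), oligodendrocyte precursor markers 3 (median 0.15), forebrain and midbrain markers 2 (median 0.044), interferon response genes 3 (median -0.012) and brainstem markers 0.

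**Figure D4:**
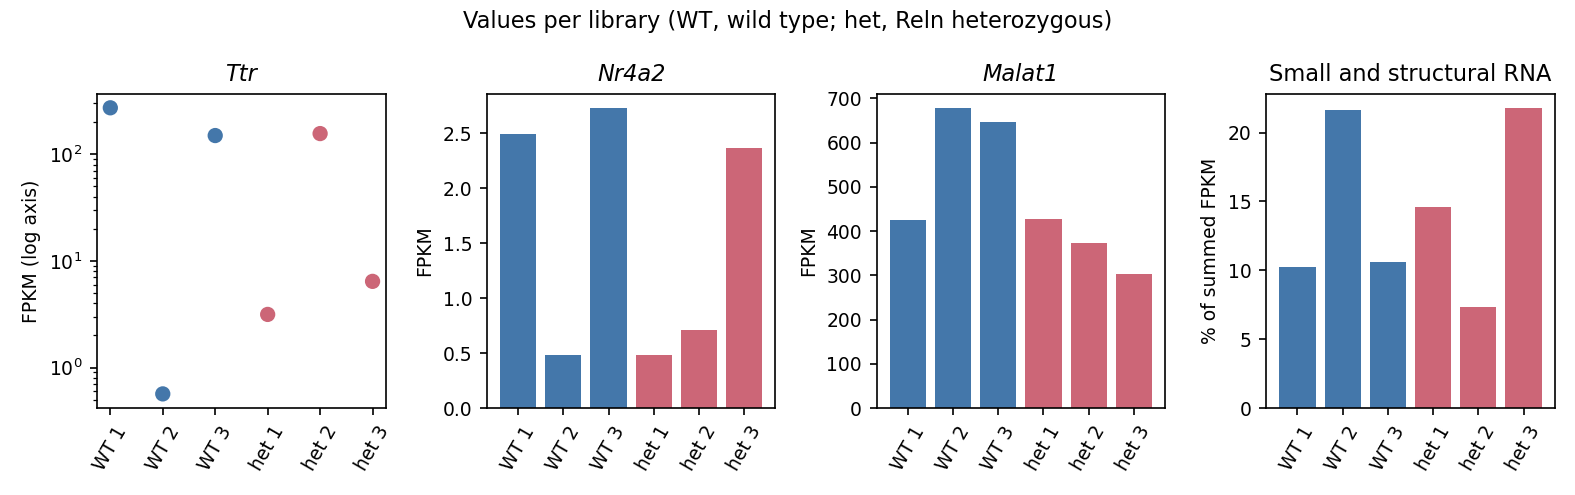
FPKM of Ttr (log axis), Nr4a2 and Malat1 and the percentage of summed FPKM taken by small and structural RNA genes, in each wild-type (blue) and Reln heterozygous (red) library. Ttr ranges from 0.566 to 273 FPKM among wild-type libraries, and the small and structural RNA share is highest in heterozygous replicate 3 (21.7%) and wild-type replicate 2 (21.6%).

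Because the strain labels differ, gene families that vary between inbred mouse strains were compared as well. The 19 tested genes of polymorphic clusters had a median of 0.11 and a mean of -0.034, and camera called them lower (adjusted p = 0.011; adjusted p = 0.91 with an estimated correlation). None passed over all genes and 3 fell adjusted over the list alone, among them Olfr856-ps1 (18.2 ± 9.8 against 9.62 ± 1.46 FPKM) and the class I gene H2-Q4 (6.71 ± 2.66 against 4.41 ± 0.77 FPKM; SD, n = 3 each). The groups overlapped for both. The log2 difference of Olfr856-ps1, -0.72, was -0.35 without wild-type replicate 2 and -1.13 without wild-type replicate 1, and that of H2-Q4, -0.46, was -0.21 and -0.69. Class I histocompatibility genes as a list (8, median 0.13, mean 0.032) had camera's direction lower, against both, with an adjusted p of 0.50, and H2-Q4 alone fell adjusted over the list alone. Genes with names of the KRAB zinc finger type (178, median 0.023), a list set by name and not by protein domain, were called lower than the other genes. Camera's adjusted p was 7.8e-06, and 0.91 with an estimated correlation. The 18 autism risk genes (median 0.0088) were called lower as well (camera adjusted p = 0.011, and 0.91 with an estimated correlation). Both lists had a median and mean above 0, under the median of all genes, and no member passed.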

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

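The alternatives without wild-type replicate 2 and heterozygous replicate 2, with the first principal component as a covariate, with a filter at 0.5 FPKM, and without small and other structural RNA genes were chosen after seeing the data. The count test set beforehand was not run, and using only genes listed in all files changed nothing. Reln stayed lower in every alternative (-0.64 to -0.23 on the log2 scale) and P4hb stayed higher (0.067 to 0.43; without 1 library, 0.15 to 0.43). P4hb passed the test only with array weights (0.33, adjusted p = 3.4e-04, range over alternatives 3.4e-04 to 1.0), a fit that did not converge and gave wild-type replicate 3 a weight of 194 and the other libraries 0.122 to 1.79.

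The count of called genes, 5 as reported, was not stable, and the cause was not tested. In limma it was 4 and 3 with pseudocounts of 0.1 and 0.01, 1 without a filter (none of the 5), 6 with a filter at 5 FPKM, which removed all 5, and 1 with the principal component (none of the 5). It was 0 with a filter at 0.5 FPKM (230 at an unadjusted p under 0.05), median-of-ratios scaling (325), quantile normalization (344), small RNA genes left out (225), small and structural RNA genes left out (326) and no trend (259). Leaving out small RNA genes removed Snora31 and Snord15a themselves, and the rescaling that went with it set the summed FPKM equal in all libraries. The count was 15 with the file set as a covariate, 67 without both libraries and 2508 with array weights (4 of the 5 in each of the last 2). Without 1 library it ranged from 5 to 62: 62 without wild-type replicate 1, 16 without wild-type replicate 3, 19, 18 and 42 without heterozygous replicates 1, 2 and 3, and 5 without wild-type replicate 2, none of them shared. Without wild-type replicate 2 the 5 genes kept their direction and lost their calls: Chac1 (0.55, adjusted p = 0.63), Zfhx2os (-0.52, 0.43), Snora31 (-0.71, 0.23), Snord15a (-0.43, 1.0) and Gm3219 (-0.68, 0.22). Gm3219 was also lost without heterozygous replicate 2 (-0.41, adjusted p = 0.55), where Chac1 fell below the filter, and Snord15a without heterozygous replicate 1 (-0.49, adjusted p = 0.097). None of the 5 changed direction in any alternative that tested it.

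Replicate numbers did not pair the libraries: same-numbered libraries correlated at -0.28, -0.52 and 0.14 in their deviations from the group means, and not every library correlated best with its own number. With the replicate block 13 genes were called, the 5 among them, and 12 lists; relative to all genes, clock genes (0.031) and matrix genes (0.033) turned in camera's direction.

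The count of called lists, 13 as reported, was 7 with a filter at 5 FPKM, 7 with array weights, 8 without both libraries, 8 with the principal component, 0 in camera with an estimated correlation (1 at an unadjusted p under 0.05) and 0 by fry (0 unadjusted); without 1 library it was 9 to 14. Ribosomal protein, oxidative phosphorylation and nuclear long noncoding RNA lists were called in all 21 alternatives of the preset test. Their size was less stable. The medians relative to all genes ranged from 0.039 to 0.19, from 0.057 to 0.15 and from -0.30 to -0.098. List values that follow are medians relative to all genes. The isomerases lost their call without heterozygous replicates 1 (0.055) and 2 (0.035) and wild-type replicate 2 (0.026), and the unfolded protein response without heterozygous replicate 2 (0.037) and wild-type replicate 2 (0.062). Granule cell markers lost it without wild-type replicates 1 (-0.062), 2 (-0.033) and 3 (-0.054) and, turned, heterozygous replicate 2 (0.023); myelin without heterozygous replicates 2 (0.092) and 3 (0.13) and wild-type replicates 2 (0.072) and 3 (0.086). Blood markers lost it without heterozygous replicate 3 (0.0071) and, turned, wild-type replicate 1 (0.18). Immediate early genes lost it without wild-type replicate 1 (-0.0035) and heterozygous replicate 1 (0.0076), autism risk genes without heterozygous replicates 1 (-0.068) and 2 (-0.050) and wild-type replicate 3 (-0.041), polymorphic clusters without wild-type replicate 2 (-0.0048) and histones without wild-type replicate 3 (0.038).

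Vldlr turned lower with median-of-ratios scaling (-0.077), quantile normalization (-0.072), small RNA genes left out (-0.099), small and structural RNA genes left out (-0.090), array weights (-0.14, adjusted p = 0.047, past the threshold in that alternative), the principal component (-0.077) and without both libraries (-0.15). Without 1 library it ranged from -0.0998 to 0.096, Lrp8, which passed with array weights (-0.11, adjusted p = 0.018), from -0.047 to 0.035 and Ttr from -3.59 to 0.14, the last without wild-type replicate 1. Camera's direction turned in 51 of 570 list values, in 17 lists, and 6 of the 51 concerned a list called before or after the change. Without both libraries these were -0.023 for the unfolded protein response, 0.035 for granule cells, 0.042 for myelin, -0.030 for astrocytes, 0.062 for the clock, -0.069 for endothelium, -0.11 for meninges and -0.063 for microglia. With array weights they were 0.45 for blood, -0.00094 for astrocytes, -0.070 for interneurons and -0.033 for Purkinje cells, and with the principal component -0.0088 for astrocytes, -0.013 for endothelium, 0.043 for glucocorticoid response and -0.066 for meninges. Without a filter they were 0.034 for brush cells and nuclei, 0.015 for endothelium, 0.019 for class I genes and 0.026 for the reelin pathway, which was at 5.3e-05 with a filter at 5 FPKM. Class I genes were at 0.039 with median-of-ratios scaling, 0.036 with quantile normalization and 0.038 with small and structural RNA genes left out. GABA and glycine receptors were at -0.0043 with quantile normalization, clock genes at 0.012 with small RNA genes left out, and matrix genes at 0.0050 and 0.0011 with pseudocounts of 0.1 and 0.01. With the file set as a covariate clock genes were at 0.075, matrix genes at -0.0066 and meninges at -0.053. Ranges without 1 library were -0.021 to 0.0998 for astrocytes, -0.46 to 0.18 for blood, -0.11 to 0.12 for brush cells, -0.073 to 0.14 for the clock, -0.035 to 0.20 for endothelium, -0.064 to 0.059 for matrix, -0.0077 to 0.17 for glucocorticoid response, -0.095 to 0.023 for granule cells, -0.084 to 0.064 for meninges (3 libraries, since the others left under 5 tested genes) and -0.00058 to 0.21 for microglia. The cause of these turns was not tested. Lists with under 5 tested genes at a filter of 5 FPKM, the isomerases, blood and autism risk genes among them, have no value there. Depth limits short genes at low FPKM: the counting error was 28% to 65.7% for Snora31 and 25.8% to 70.8% for Snord15a, against 5.64% to 8.03% for Reln.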

Other observations

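The tests of the scale of the values, of the granule cell share and of 2-fold differences at a mean of at least 1 FPKM were chosen after the results they measure had been seen; the other tests were chosen before.

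The 15 immediate early genes had a median of 0.048 and a mean of -0.067, and camera called them lower (adjusted p = 0.031; adjusted p = 0.91 with an estimated correlation), with 9 higher and 6 lower in heterozygous libraries and none past the test singly or adjusted over the list alone. Nr4a2 stood at 2.49, 0.481 and 2.73 FPKM in wild-type replicates 1, 2 and 3 and at 0.484, 0.708 and 2.37 FPKM in heterozygous replicates 1, 2 and 3, and Npas4 at 1.94, 0.371 and 1.61 FPKM and at 0.220, 1.10 and 1.17 FPKM. Klf10 went the other way, at 1.41, 1.30 and 1.251 FPKM and at 1.94, 2.57 and 0.968 FPKM (0.24, limma adjusted p = 0.90; 0.48 and 0.020 without heterozygous replicate 3, 0.053 and 1.0 without heterozygous replicate 2). Clock genes (12, median 0.11, camera's direction lower against it, adjusted p = 0.86) and glucocorticoid response genes (8, median 0.15, adjusted p = 0.75) were not called. Neither were glutamate receptor genes (6, median 0.036, direction lower, adjusted p = 0.13), GABA and glycine receptor genes (7, median 0.11, adjusted p = 0.51), synaptic vesicle and scaffold genes (18, median 0.019, direction lower, adjusted p = 0.11) and matrix genes (7, median 0.12, direction lower, adjusted p = 0.99). In these 6 lists no gene passed over all genes or adjusted over the list alone.

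The first principal component of the libraries held 63.9% of the variance, with wild-type replicate 2 (17.6) and heterozygous replicate 2 (-14.4) at its ends, so the main axis did not follow genotype. Correlations between libraries, across genes, were 0.982 to 0.993 within groups and 0.979 to 0.992 between them; genes are not independent replicates. Splitting the 6 libraries in each of the 10 possible ways gave as many genes as the real split, 5, in 8 of them, the real one included, and the highest other split, wild-type replicate 1 with heterozygous replicates 2 and 3 against the rest, gave 92, which points to a structure of the samples; what lies behind it was not tested. For gene lists 5 of the 10 splits gave as many as the real 13, and the highest other gave 18. With 10 splits no share under 0.05 can be reached. RNase P and RNase MRP RNA (Rpph1 and Rmrp, chosen after their values were seen) took 9.10%, 18.8% and 9.14% of the summed FPKM in wild-type replicates 1, 2 and 3 and 12.998%, 6.50% and 19.4% in heterozygous replicates 1, 2 and 3.

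Reln was lower in each heterozygous library, with a log2 ratio of mean FPKM of -0.65. The tables argue against a library-wide scale as its cause, since the ratio was -0.77 after median-of-ratios scaling, still without overlap. They also argue against a lower share of granule cells, which would lower their markers alike. The median log2 ratio of these markers was 0.032, against -0.65 for Reln, both on FPKM as deposited. Relative to all tested genes, their median difference in log2(FPKM + 1) was -0.053, against -0.26 for Reln before any such adjustment. Camera called the markers lower (adjusted p = 0.043, and 0.91 with an estimated correlation). Of 4357 genes with 0.35 to 1.4 FPKM, 40 had as low a ratio, Reln included, and in 7 of these, Reln among them, the groups did not overlap. The genotype and a difference of the labelled strains at the locus both stay open, untested, since they coincide in every library.

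Ribosomal protein genes were higher and nuclear long noncoding RNAs lower than the other genes, by list medians of 0.12 and -0.17 relative to all tested genes. The scale of the FPKM values could not be tested on the first, since a factor on all genes nearly cancels in a median relative to all genes. By that construction, dividing all heterozygous values by 1.06, the shift of all genes, moved it from 0.12 to 0.098. After median-of-ratios scaling it was 0.088 and passed camera with the preset correlation (adjusted p = 1.0e-10). Neither list pattern was removed with the first principal component as a covariate. The relative medians were then 0.11 (camera adjusted p = 3.9e-15) and -0.12 (camera adjusted p = 0.0024), with the preset correlation. The groups overlapped in the list means of both, and neither passed with an estimated correlation. A difference between these particular libraries other than the group therefore stays open. Differences in RNA preparation were not tested. No biological explanation was tested.

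Few genes separated the groups although their labelled strains differ. The counts that follow are on FPKM after median-of-ratios scaling, for 12221 genes with a mean of at least 0.1 FPKM. The real split had 9 genes at least 2-fold apart without overlap, against a median of 10 and a highest of 63 in the other splits, 6 of which had as many. Of the 9 genes, 8 had a mean under 1 FPKM and 3 were at 0 in every library of 1 group, and the split with 63 set the 3 libraries with high Ttr against the rest. With a mean of at least 1 FPKM the real split had 1 gene, against a median of 2 and a highest of 19. A whole-genome difference of background was set to show as more genes in the real split than in any other. That bound was wrong, since values near the floor fill the count of the real split, and the highest count came from the split that followed Ttr. These counts do not exclude a difference of background. What fills the counts of the other splits was not tested. Within 10000000 bases of Reln the groups did not overlap in 11.8% of the 102 of these genes with a position, against 10.3% of 11855 elsewhere (Fisher's exact p = 0.62) and 10% by chance, so a strain segment around Reln cannot be told apart from none with so few genes. Sequence variants were not used here.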
